A study of Arabidopsis thaliana with 4 samples.

How the data were processed

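Gene expression was measured in whole Arabidopsis thaliana seedlings of the Columbia ecotype that carried the pER8-LEC1 transgene, in which estradiol switches on LEAFY COTYLEDON1 (LEC1), a transcription factor of embryo development. Per the labels, seeds were germinated and grown for 4 days on medium with 10 µM (0.01 mM) estradiol, called LEC1 induced here, or with 0.1% DMSO, called control. Each group had 2 biological replicates, so 4 arrays were analysed. RNA was amplified by a 2-cycle protocol and hybridized to Affymetrix ATH1 arrays, per the labels' protocols. Seedlings given estradiol without the transgene are not among these 4 arrays.

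The deposited values are linear signal intensity values, 1 per probe set and array, and MAS5 is the tool named in the submitters' processing notes. The scaling target and the detection calls are not given in the sources used here. Per the series' design text, the submitters removed genes that were absent everywhere, ran a two-sided test per gene, adjusted with the Benjamini-Hochberg method and took a false discovery rate under 0.2.

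The table held 22810 probe sets, of which 64 were array controls and were left out of the tests. Values under 0.1 (8 values) were set to 0.1 before taking log2. A probe set was kept if its signal was above the 40th percentile of its own array in at least 2 arrays, which kept 14433 of 22746. The plan made before the data were examined assumed arrays already on 1 level and used no further normalization. The array medians turned out to differ, from 15.5 to 39.4, so the log2 values were quantile normalized between arrays, and this was decided before any test was run. The unnormalized values became an alternative, chosen after the table was opened.

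Probe sets were named from a platform annotation, with symbols updated through the gene table of assembly TAIR10.1. Of the probe sets that were not controls, 13513 named 1 gene, 503 named several and 8730 were unnamed here, and 13436 of the first kind matched a locus in the gene table. No gene was named from a probe set with several genes. Gene positions are not given, because the deposited table names no genome build. LEC1 itself, LEC2, FUS3, ABI3, WRI1, ABI5 and NF-YB6 have no probe set named for them alone in this annotation, and their levels are not analysed here. Gene ontology terms were not analysed here either.

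Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), two-sided, with Benjamini-Hochberg adjustment over all kept probe sets and a threshold of 0.05. Errors of log2 changes are limma's standard errors. The replicates left 2 residual degrees of freedom, to which the moderated fit added a prior worth 4.39. Only 2 arrays per group limit the precision. The 40th percentile of the normalized signals, 13.9, is called the dim limit here. Where an array of the lower group was under it, a fold is given only as a lower bound, the mean of the brighter group against the mean of the lower group with each array set to at least the limit. Medians of lists with such genes are also given with all signals under the limit set to it.

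Gene lists were tested with limma's camera with a preset correlation between genes of 0.01, using the brightest probe set of each of 7655 genes. A list was tested when at least 3 members were measured, meaning that a probe set naming that gene alone passed the filter. A gene under the filter's cut on both control arrays was kept only where both induced arrays were above it. Counts of measured members thus leave out genes dim in both groups. Of 67 genes with several kept probe sets, 18 had probe sets that differed in sign, 1 had probe sets that differed in call, and 0 were called both ways. The plan also fixed 20 lists with 323 genes, called planned lists. Because few of their members were named on the array, 15 further lists were drawn up from gene names alone after the table had been opened and before any test, and they are called added lists. In all, 22 lists had enough members, and p-values were adjusted over these 22. With the correlation estimated from the residuals, 0 of the 22 lists passed 0.05. That form of the test rests on the 2 residual degrees of freedom, which by itself limits how small its p-values can be. Estimated correlations ranged from -0.359 to 0.924, and lists below the preset value did not pass either. These p-values therefore cannot show whether correlation between genes accounts for a shift.

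Named genes followed a rule in the same plan. It took LEC1 and a set of embryo regulators, the 8 largest rises and the 8 largest falls among called probe sets naming 1 gene whose groups did not overlap and whose brighter mean was above the array median, up to 4 called members of each core list and up to 2 of each other list. Where a list had no called member, its brightest member was taken. The order of the large rises and falls rests in part on signals under the dim limit and is not read as a ranking. Further members are named only where a count is 5 or fewer, and those were chosen after their values were seen.

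The steps were tested on simulated data made from the real means and limma's moderated standard deviations, which are pulled toward its mean-variance trend. In these data 200 probe sets were changed by known amounts, and 14073 were tested. For this comparison, limma recovered 4% of changes of 1 on the log2 scale, 50% of changes of 2, 88% of changes of 4 and 100% of changes of 8, with 7 false calls. Camera gave a p of 3.24e-08 for 8 genes shifted by 1, and 1 of 100 unchanged sets passed 0.05. The simulated noise was independent between probe sets, so this rate does not carry over to lists whose genes vary together. It followed the fitted model and held no deviation shared by same-numbered arrays. Recovery and false calls may thus be less favourable in the real data. Estimated correlations in the real lists reached 0.924, for late embryogenesis abundant proteins. Alternatives covered the scaling, an offset before log2, the variance prior, the filter on dim probe sets, the replicate number as a block, each array left out in turn, signals under the dim limit set to it (added after the results were seen), other thresholds, the methods' t-test and other set tests.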

Results

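Expression was compared between seedlings in which LEC1 was induced with estradiol for 4 days and control seedlings on DMSO, with 2 arrays in each group. The series' title names the question, the part LEC1 plays in fatty acid biosynthesis. As deposited, the median signal was 20 and 15.5 on the control arrays and 39.4 and 22.3 on the induced arrays. Over kept probe sets, log2 signals correlated at 0.909 between the controls and 0.888 between the induced arrays, across probe sets, which are not independent replicates. Between groups the same correlation was 0.681 to 0.774. The induced gene could not be used to check the labels, since its level is not analysed here.

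LEC1-induced seedlings carried high levels of several seed transcripts, and some of these, such as PAP85, had control signals under the dim limit. PAP85 (AT3G22640), a vicilin-like seed storage protein gene, rose at least 399-fold to a mean signal of 5540 (log2 signal 12.44 ± 0.13 SD in n = 2 induced arrays, limma adjusted p = 4.06e-05). The oleosin gene AT3G01570 rose to a signal of 5651, at least 407-fold, and OLEO3 (AT5G51210), which encodes another coat protein of oil bodies, rose 133-fold from 39.8 to 5283. At the same time many transcripts of photosynthesis were lower. The largest fall among them was that of the plastid gene rbcL for the large subunit of Rubisco. It fell by 4.36 ± 0.51 SE on the log2 scale, from 1092 to 53.1 (limma adjusted p = 0.0114). Changes in its list were uneven and reached -0.04 for atpE, and poorer capture of organelle RNA stays open for these genes. The nuclear photosystem list had a median of -0.96, with 1 of 6 measured genes called. The 8 measured genes of plastid fatty acid synthesis, of 30 listed, were higher by a median of 1.17 on the log2 scale. Of these 8, 2 passed over all probe sets. Their median depended on scaling, at 0.867 under median centring and 1.565 without normalization.

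Across the genome, 828 of 14433 probe sets changed in limma, 408 upward and 420 downward. All 828 had both induced arrays on the same side of both control arrays, which with 2 arrays per group follows largely from the call itself. Of all kept probe sets 58.3% showed this pattern, which chance gives in 33.3%. Among the 828, 203 rises and 211 falls belonged to probe sets naming 1 gene. The split depended on scaling: as deposited, without normalization, 494 rose and 97 fell, with the median of all kept probe sets shifted by 0.62, and after median centring 478 rose and 846 fell, with a shift of -0.08. Values below are relative to a median shift of 0. Spike signals also differed by replicate number, and added poly-A spike RNA was 4.17 times brighter on control replicate 1 than on control replicate 2 and 2.68 times brighter on induced replicate 1 than on induced replicate 2. With the replicate number as a block, 2583 probe sets changed, including all 828. Leaving out an array gave 163 calls without control replicate 1, 147 without control replicate 2, 1803 without LEC1 induced replicate 2 and 1075 without LEC1 induced replicate 1, where 694 fell.

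Seed storage and oil body genes were among those that rose. Of 11 listed storage protein genes 3 were measured and 2 rose, PAP85 and the vicilin-like gene AT2G28490 (at least 284-fold, limma adjusted p = 0.00261), and adjusted over the list alone the count was also 2. The remaining member, AT2G18540, had a signal of 2.24 in controls and 24.6 in induced seedlings and did not pass (limma adjusted p = 0.236). All 3 had control signals under the dim limit. The list's fitted median log2 change was 11.80 (camera adjusted p = 8.24e-05, and adjusted p = 0.218 with an estimated correlation). With such signals set to the limit it was 8.15 (camera adjusted p = 6.76e-05), with 8.32 between the replicate 1 arrays and 7.98 between the replicate 2 arrays. Both measured oil body genes, of 15 listed, rose, over all probe sets and adjusted over the list alone. The added list of further oleosin and seed cupin loci had 4 rises among 5 measured members, AT4G36700 (at least 237-fold), AT1G03890 (at least 324-fold), AT3G18570 and AT2G25890, and the same number adjusted over the list alone. The remaining member, AT1G07750, differed by 0.14 (limma adjusted p = 0.86). The list's median was 5.78 (camera adjusted p = 1.54e-05, and adjusted p = 0.218 with an estimated correlation), and 5.14 with signals set to the dim limit (camera adjusted p = 5.08e-06). The call of AT2G25890 was lost without control replicate 2 (limma adjusted p = 0.105) and without LEC1 induced replicate 1 (0.0596), and also without the filter (0.0534), with a robust prior (0.0542) and with a prior without a trend (0.0773).

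**Figure D1:**
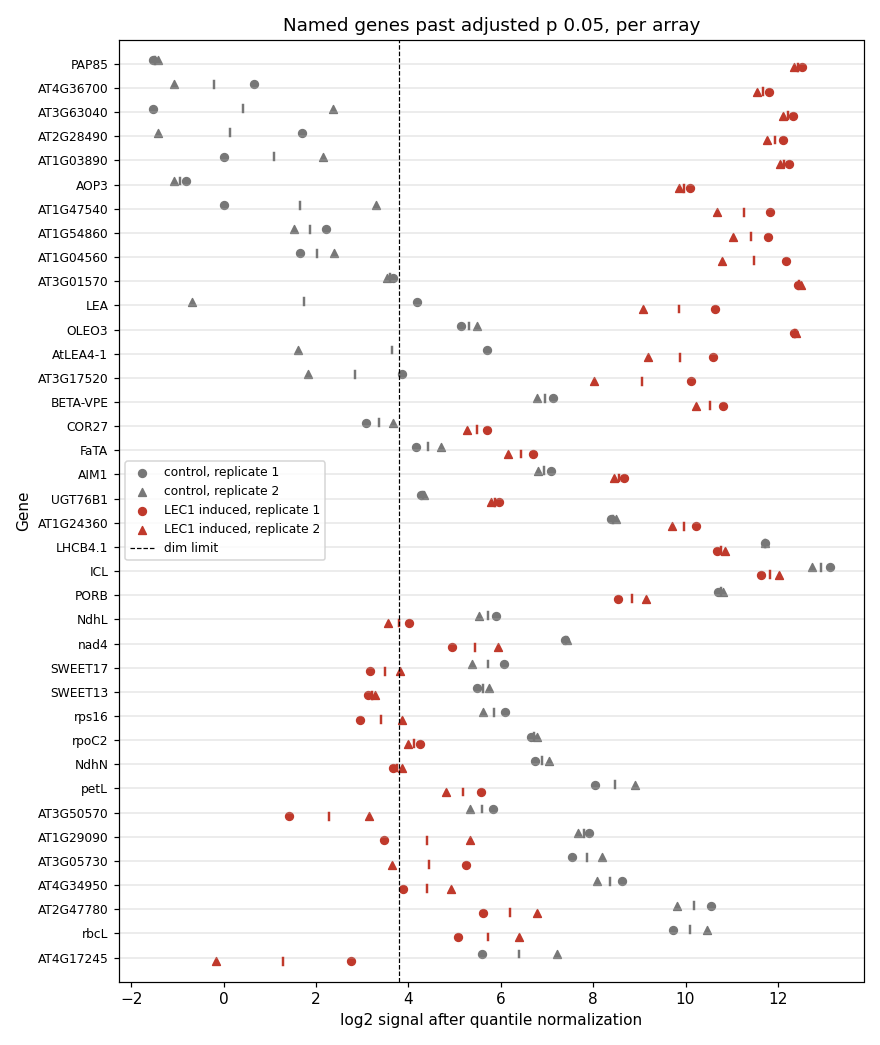
Each point is 1 array's log2 signal after quantile normalization (horizontal axis) for a gene named by rule that passed limma's adjusted p of 0.05, ordered by change, each short bar is the mean of 2 arrays, and the dashed line is the dim limit. Seed genes such as PAP85 lie at the top, with control signals under the limit and induced means up to 5651, and falls such as rbcL (1092 to 53.1) lie at the bottom.

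Late embryogenesis abundant (LEA) genes, whose products accumulate as seeds dry, were also higher. Of 18 listed LEA genes 9 were named on the array and 6 were measured. Of these 6, 2 rose, AtLEA4-1 (at least 35.3-fold, to a signal of 947.6, limma adjusted p = 0.0415) and AT3G17520 (at least 37.5-fold, to 534.3, limma adjusted p = 0.0197), each with 1 of 2 control arrays under the dim limit. Adjusted over the list alone 3 rose. All 6 were higher in induced seedlings, with a median log2 change of 3.82 (camera adjusted p = 6.50e-04, and adjusted p = 0.375 with an estimated correlation), and of 2.25 with signals set to the dim limit (camera adjusted p = 0.00221). The list did not pass fry's directional or mixed test (adjusted p = 0.167 and 0.0986). The calls of AtLEA4-1 and AT3G17520 were lost without control replicate 2, at limma adjusted p = 0.0694 and 0.0786, and that of AtLEA4-1 also without the filter (0.052), with a robust prior (0.0568) and with a prior without a trend (0.0807). With the replicate number as a block all 6 passed (limma adjusted p up to 0.0479). In the added list of further LEA and seed maturation loci, 14 members were named on the array and 7 were measured. Of these 7, 5 rose, AT1G04560 (at least 207-fold), AT2G21490 (given as LEA in the annotation, at least 58.7-fold), AT5G44310, AT4G21020 and AT3G02480. Adjusted over the list alone 6 rose, and 6 with the replicate block. The list's median was 4.33 (camera adjusted p = 5.79e-06, adjusted p = 0.279 with an estimated correlation, and 0.0738 in fry's directional test), and 3.14 with signals set to the dim limit (camera adjusted p = 5.08e-06). Without control replicate 1, the limma adjusted p was 0.0932 for AT4G21020 and 0.0798 for AT3G02480. Without control replicate 2 these were 0.0836 and 0.141, and AT5G44310 gave 0.0513 without LEC1 induced replicate 1.

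Among embryo and maturation regulators, EEL and BZIP53 were measured. EEL (AT2G41070), a bZIP transcription factor of seed maturation, rose at least 20.4-fold, to a signal of 282.6 (limma adjusted p = 0.0036), while BZIP53 differed by 0.31 ± 0.43 SE and did not pass (limma adjusted p = 0.67). Its sign turned under median centring, to -0.086. Adjusted over the list alone, EEL was again the 1 rise. BBM, an embryo transcription factor, was too dim for the test. Its signals as deposited, before normalization, were 5.6 and 0.7 in controls and 30.9 and 9.2 in induced seedlings. Other genes with large rises were AT3G63040, AOP3, AT1G47540 and AT1G54860, with mean induced signals of 4763, 1010, 2438 and 2722 and limma adjusted p-values of 0.00583, 1.06e-04, 0.00804 and 1.65e-04. AOP3 is a member of the glucosinolate AOP gene family.

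Of 30 listed plastid fatty acid synthesis genes, 8 were measured and the others are not analysed here. These 8 were higher in induced seedlings. Over all probe sets 2 rose, FaTA (AT3G25110), an acyl-ACP thioesterase that releases fatty acids from their carrier (3.99-fold, from 21.6 to 86.4, limma adjusted p = 0.0349), and AT1G24360, a ketoacyl-ACP reductase of the elongation cycle (2.90-fold, from 346 to 1004, limma adjusted p = 0.0379). Adjusted over the list alone 5 rose, which adds AT4G13050, AT4G16155 and AT2G34590, 3.16-fold, 2.26-fold and 2.25-fold higher, and without normalization AT4G13050 also passed over all probe sets (limma adjusted p = 0.0479). With the replicate number as a block all 3 passed over all probe sets (0.0316, 0.0321 and 0.0229). Without LEC1 induced replicate 2, AT4G13050 and AT2G34590 passed (0.0358 and 0.0372), and without LEC1 induced replicate 1, AT4G16155 and AT2G34590 did (0.0462 and 0.0468). AT2G34590 also passed with an offset (0.0497) and with the stricter filter (0.0492). The list's median was 1.17, with 1.06 and 1.04 within replicates 1 and 2 (camera adjusted p = 1.81e-04, and adjusted p = 0.218 with an estimated correlation). The call of AT1G24360 was lost without normalization (limma adjusted p = 0.0883), under median centring (0.0844), without control replicate 1 (0.203) and without control replicate 2 (0.192). The call of FaTA was lost without control replicate 1 (0.178), control replicate 2 (0.116) and LEC1 induced replicate 1 (0.0644). In storage lipid breakdown, of 3 measured genes AIM1, a beta-oxidation enzyme, rose 3.04-fold (limma adjusted p = 0.0378), ICL, the glyoxylate cycle's isocitrate lyase, fell by 1.09 on the log2 scale from 7776 to 3654 (limma adjusted p = 0.0415), and SDP1 differed by 0.34 ± 0.35 SE (1.002 without normalization). Adjusted over the list alone, 1 rose and 1 fell, and the list did not shift in 1 direction (camera adjusted p = 0.734). It passed fry's mixed test, which counts changes either way (adjusted p = 0.0153). The calls of AIM1 and ICL were lost without normalization (limma adjusted p = 0.0621 and 0.275), without control replicate 1 (0.178 and 0.19) and without control replicate 2 (0.24 and 0.111).

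Photosynthesis genes of the nucleus were mostly lower in induced seedlings. In the list of photosystems and light harvesting, 6 of 36 genes were measured and 1 fell, LHCB4.1, a light-harvesting protein of photosystem II (by 0.94 ± 0.19 SE on the log2 scale, from 3345 to 1741, limma adjusted p = 0.0446), and 5 fell adjusted over the list alone. The list's median was -0.96 (camera adjusted p = 0.00182, and adjusted p = 0.240 with an estimated correlation). It was -1.65 under median centring and -0.96 without normalization. In carbon fixation and chlorophyll synthesis, 5 of 22 were measured and 1 fell, PORB, a protochlorophyllide reductase (from 1738 to 458.7, limma adjusted p = 0.0230), and 3 fell adjusted over the list alone. That list's median was -1.10 (camera adjusted p = 0.0136, and adjusted p = 0.422 with an estimated correlation), and its call was lost without control replicate 2 (camera adjusted p = 0.099) and in fry's directional test (adjusted p = 0.167). With the replicate block 5 and 3 members of these lists fell. Of 19 measured members of the added list of nuclear-encoded plastid electron transport accessories, 3 fell, NdhN, NdhL and CYTC6A, and 16 were lower. Adjusted over the list alone 14 fell and 2 rose, PGRL1B and LHCB4.3, which did not pass over all probe sets (log2 changes 1.25 ± 0.32 SE and 1.11 ± 0.37 SE, limma adjusted p = 0.0727 and 0.125) but passed with the replicate block (0.0323 and 0.0302), where 9 fell. Its median was -0.95 (camera adjusted p = 7.92e-05, and adjusted p = 0.240 with an estimated correlation). LHCB4.1 was not called without normalization (limma adjusted p = 0.2), nor were NdhL (0.27) and CYTC6A (0.259). Without control replicate 1 or 2, the limma adjusted p was 0.224 or 0.24 for LHCB4.1, 0.138 or 0.161 for PORB, 0.187 or 0.144 for NdhL and 0.167 or 0.14 for CYTC6A, and NdhN was lost without control replicate 2 (0.0593).

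Transcripts encoded in the organelles were lower as well. In the added list of plastid-encoded photosynthesis genes, 14 of 42 measured members fell and 0 of 42 were higher, with 28 falls adjusted over the list alone and 35 over all probe sets with the replicate block. Among the 14, the largest falls were those of rbcL and petL, a subunit of the cytochrome b6f complex (from 353.4 to 36.4, limma adjusted p = 0.0169). The median was -1.89, with -1.77 and -1.99 within replicates 1 and 2 (camera adjusted p = 4.66e-15, and adjusted p = 0.218 with an estimated correlation), and -1.74 with signals set to the dim limit (camera adjusted p = 2.44e-13). Plastid-encoded gene expression genes had 4 falls among 19 measured, or 9 adjusted over the list alone and 13 with the replicate block, and rpoC2, an RNA polymerase subunit, went from 105 to 17.5 (limma adjusted p = 0.012) and the ribosomal protein gene rps16 from 58.2 to 10.7 (limma adjusted p = 0.0349). Their median was -1.53 (camera adjusted p = 2.16e-07, and adjusted p = 0.218 with an estimated correlation). Of 9 mitochondrion-encoded genes, 1 fell, nad4 (from 170.5 to 43.6, limma adjusted p = 0.0466), 6 fell adjusted over the list alone and 3 with the replicate block. Their median was -1.34 (camera adjusted p = 3.53e-04, adjusted p = 0.375 with an estimated correlation, and 0.0903 in fry's directional test), and -1.08 with signals set to the dim limit (camera adjusted p = 1.72e-04). The 3' to 5' signal ratio of the actin control probe sets also differed by group, at 3.28 and 3.01 in controls and 1.96 and 1.94 in induced seedlings, while that of GAPDH was 0.773 and 0.890 against 0.932 and 0.911. Without normalization rpoC2, rps16 and nad4 were not called (limma adjusted p = 0.0783, 0.116 and 0.15). Without control replicate 1 or 2, the limma adjusted p was 0.0528 or 0.0941 for petL, 0.0771 or 0.0826 for rpoC2, 0.174 or 0.13 for rps16 and 0.189 or 0.2 for nad4, and rbcL was lost without control replicate 2 (0.079).

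**Figure D2:**
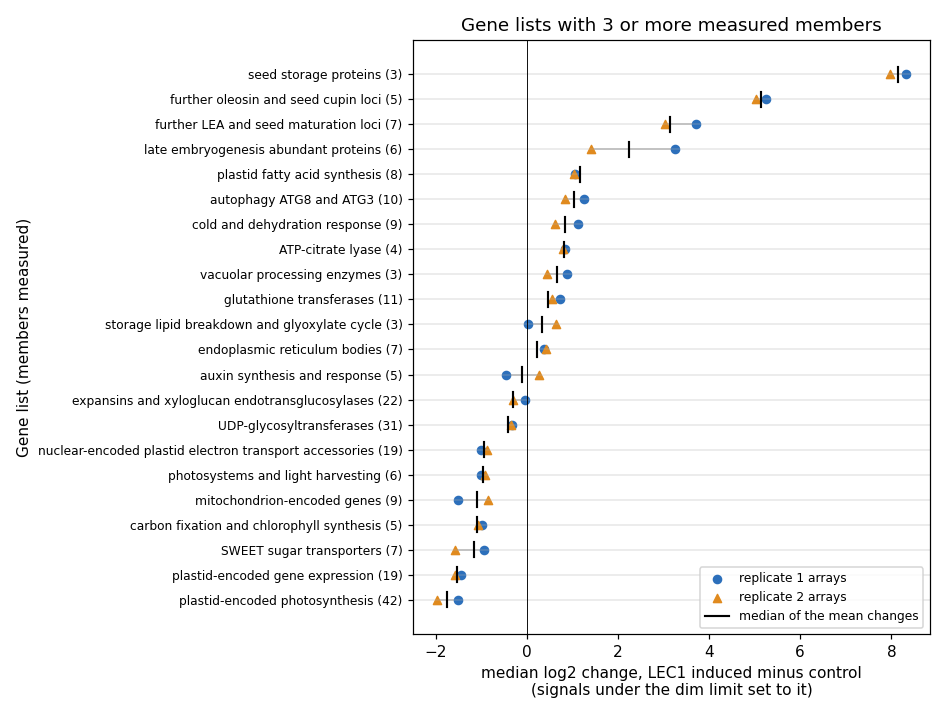
Median log2 change, induced minus control (horizontal axis), of each gene list with 3 or more measured members (number in parentheses), within the replicate 1 arrays (circles), within the replicate 2 arrays (triangles) and of the mean changes (black bars), with signals under the dim limit set to it. Seed lists lie to the right, at 2.25 to 8.15, and plastid-encoded lists to the left, at -1.74 and -1.53.

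Other genes with large falls were AT4G17245, AT2G47780, AT4G34950, AT3G05730, AT1G29090 and AT3G50570, of which AT4G17245 and AT3G50570 had both induced arrays under the dim limit. AT2G47780 went from 1166 to 73.6 and AT4G34950 from 327.8 to 21.2 (limma adjusted p = 0.012 and 0.0101). Without control replicate 1 the limma adjusted p of these 6 ranged from 0.0658 to 0.203, so the calls of all 6 were lost. Without control replicate 2 those of AT4G17245, AT2G47780, AT3G05730, AT1G29090 and AT3G50570 were lost at 0.0578 to 0.243, and AT4G34950 was kept at 0.0471. AT3G50570 was also not called without normalization (0.0813).

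Calls of single genes also depended on the variance prior and the filter. With a prior without a trend, limma adjusted p-values were 0.0574 to 0.144 for AT4G17245, AT3G05730, AT1G29090, AT3G50570, FaTA, AT1G24360, LHCB4.1, PORB, AIM1, ICL, rps16, nad4, NdhL, CYTC6A, AT2G21490 and AT3G02480, so none of these was called. Without the filter AT4G17245, AT3G50570, FaTA, LHCB4.1, ICL, rps16, nad4, NdhL and CYTC6A were not called (limma adjusted p = 0.053 to 0.247), and with the stricter filter AT4G17245, AT3G50570 and NdhL were not (0.0505 to 0.0652). With signals under the dim limit set to it AT4G17245, FaTA, LHCB4.1, ICL and nad4 were not called (0.0511 to 0.07).

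Other planned lists had few measured members. The anthocyanin genes DFR and UF3GT had signals of 223.4 and 261.3 in controls and 21.7 and 24.2 in induced seedlings, with 1 of 2 induced arrays under the dim limit. Neither passed over all probe sets (limma adjusted p = 0.0569 and 0.0554), and both fell adjusted over the list alone. Both passed over all probe sets with the replicate number as a block (0.00891 and 0.00158), without normalization (0.022 and 0.0167), under median centring (0.0348 and 0.0311), with an offset (0.0402 and 0.0427), without LEC1 induced replicate 1 (0.0108 and 0.0253) and without LEC1 induced replicate 2 (6.69e-04 and 0.00271). The root hair expansin genes EXPA18 and EXPA7 had log2 changes of -1.75 ± 0.41 SE and -1.23 ± 0.44 SE (limma adjusted p = 0.0594 and 0.142), both fell adjusted over the list alone, and EXPA18 passed over all probe sets with the block (0.0125), under median centring (0.0311) and with a robust prior (0.0498). Without LEC1 induced replicate 2 both passed (0.00948 and 0.0355). Auxin synthesis and response genes had 0 of 5 past the threshold in limma, over all probe sets or adjusted over the list alone, with WES1 at a log2 change of -0.06 ± 0.35 SE, a sign that turned without normalization (0.45). Their median was -0.11 (0.43 without normalization), their mean 0.41, and camera's direction was down (adjusted p = 0.607). The auxin list passed fry's mixed test, which counts changes either way (adjusted p = 0.00742). AT1G53540 (heat shock, signals 13.6 and 5.37 in control and induced seedlings), GSTU25 (detoxification, log2 change 0.47 ± 0.39 SE), PDF1.2 (defence, signals 22.9 and 9.35), AUR1 (cell cycle, 0.34 ± 0.48 SE) and PEX4 (reference gene, -0.17 ± 0.32 SE, 0.37 without normalization) were the only measured members of their lists, and none passed over all probe sets or adjusted over the list alone. The lists of carbon supply, hormone metabolism, epidermis, and seed coat and endosperm had 0 measured members.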

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

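Tests without normalization and of the added lists were chosen after the table was opened, and the test with signals set to the dim limit after the results were seen. Of 7 planned lists 5 were called, 0 with an estimated correlation, 3 with fry's directional test, 6 with its mixed test (4 of them among the 5), and 4 to 5 without 1 array. Without the filter 6 of 8 were called and with the stricter filter 4 of 5, since other numbers of lists had enough members. The added lists gave 12 calls of 15, 8 with fry's directional test, 12 with its mixed test, 8 without normalization and 7 without control replicate 2. Among the added lists the mixed test lost cold and dehydration and autophagy, and it gained endoplasmic reticulum bodies and UDP-glycosyltransferases. The number of changed probe sets moved more than the list calls. Without normalization 97 fell. Median centring gave 1324 changes with 846 falls, a variance prior without a trend gave 381 (233 up, 148 down), and a threshold of 0.2 gave 3981 (1897 up, 2084 down). The methods' t-test gave 396 calls at 0.2 (189 up, 207 down) and 2 at 0.05, 1 each way, with 2494 probe sets at an unadjusted p under 0.05, and of the 828 changed in limma it called 180 at 0.2. Leaving out 1 array gave 147 to 1803 changes, 141 to 700 rises and 6 to 1103 falls, with the lone array assumed to vary like the other group. Fewer arrays leave fewer degrees of freedom, and the cause of the other differences was not tested. With the replicate block, 2583 probe sets changed (1178 up, 1405 down), including all 828. The deviations of same-numbered arrays correlated at 0.311 across probe sets, but the labels do not say what a number shares, and the block changed no list call. With signals under the dim limit set to it 741 changed (665 of the 828), and no list call changed. Among 68 named genes, 45 were called. Of these 21 were lost with a prior without a trend, 15 without the filter, 12 without normalization, 6 at the dim limit, 5 with the stricter filter, 2 with a robust prior, 1 under median centring and 0 with the block, which added 11. Of the 45, 21 stayed called without control replicate 1, 17 without control replicate 2, 39 without LEC1 induced replicate 1 and 43 without LEC1 induced replicate 2.

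Changes of sign were seen only among results that had not passed. Under median centring the log2 change was -0.14 for EXPA4, -0.48 for PYK10, -0.086 for BZIP53 and -0.20 for the median of the endoplasmic reticulum body list. Without normalization WES1 was at 0.45 and PEX4 at 0.37. With 1 array left out, WES1 lay between -0.39 and 0.28, AT1G53540 between -3.004 and 0.36, AUR1 between -0.18 and 0.85 (also -0.082), EXPA4 between -0.026 and 0.36, and BZIP53 between -0.16 and 0.80 (also -0.037). The test's direction turned for auxin genes without control replicate 1 (median -0.047, with medians from -0.60 to 0.16 over left-out arrays) and with fry (median -0.11), and for storage lipid breakdown without control replicate 2 (median 0.00139, up to 0.65 without control replicate 1). The cause was not tested. The level of LEC1 and gene ontology terms could not be recomputed here, and signal near the bottom of the range limits folds to lower bounds.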

Other observations

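Tests of delayed germination, scaling of plastid gene expression and mitochondrial genes, organelle RNA capture, a lower plastid programme and array brightness were chosen after the results were seen, as was the setting of signals to the dim limit. The values without normalization and the added lists, which the first paragraphs describe, were chosen after the table was opened and before any test.

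Several other gene groups differed between induced and control seedlings. Of 14 SWEET sugar transporter genes named on the array 7 were measured, and 7 of 7 were lower. SWEET13 and SWEET17 fell at least 3.53-fold and 3.77-fold (limma adjusted p = 0.0258 and 0.0409), while 4 fell adjusted over the list alone and 4 with the replicate block. The list's median was -1.92 (camera adjusted p = 3.53e-04, and adjusted p = 0.218 with an estimated correlation), and -1.15 with signals set to the dim limit (camera adjusted p = 8.64e-04). Without normalization these members were not called (limma adjusted p = 0.135 and 0.164), nor without control replicate 1 (0.119 and 0.194) or control replicate 2 (0.145 and 0.116), and SWEET17 was not called without LEC1 induced replicate 1 (0.0515), with a prior without a trend (0.0622) or with the stricter filter (0.0517). Without the filter neither was called (0.0521 and 0.0756). BETA-VPE, a vacuolar processing enzyme that matures seed storage proteins, rose 11.8-fold from 124 to 1466 (limma adjusted p = 0.00501), and it passed in each setting that left out 1 array (limma adjusted p up to 0.0488). The 3 measured vacuolar processing enzymes had a median of 0.66 (camera adjusted p = 0.0299, and adjusted p = 0.279 with an estimated correlation), which did not pass without normalization (0.0575) or without control replicate 2 (0.0743). Autophagy genes (ATG8 and ATG3) had 9 of 10 members higher and a median of 1.27 (camera adjusted p = 0.00386, and adjusted p = 0.442 with an estimated correlation), or 1.03 with signals set to the dim limit (camera adjusted p = 0.00431). Singly 0 passed in limma, and with the replicate block 5 rose (ATG3, APG8H, ATG8D, ATG8C and ATG8H). APG8H is the annotation's symbol for AT3G15580, a separate locus from ATG8H. The list's median was 0.697 without LEC1 induced replicate 1 and 0.855 without control replicate 2. The list's call was lost without LEC1 induced replicate 1 (0.0733), without control replicate 2 (0.0597) and in fry's directional and mixed tests (adjusted p = 0.267 and 0.163).

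Smaller list shifts were less stable. Cold and dehydration genes (median 0.85, camera adjusted p = 0.0261), glutathione transferases (0.66, 0.033) and ATP-citrate lyase (0.82, 0.0299) passed, and none of these 3 passed without normalization (camera adjusted p = 0.138, 0.0981 and 0.185), under median centring (0.13, 0.0532 and 0.185) or without control replicate 2 (0.0743 for all 3). Without control replicate 1 the camera adjusted p was 0.0682 for glutathione transferases and 0.117 for ATP-citrate lyase, without LEC1 induced replicate 2 it was 0.0825 and 0.111, and cold and dehydration genes gave 0.296 without LEC1 induced replicate 1 and 0.0762 with the stricter filter. With an estimated correlation their adjusted p was 0.442, 0.279 and 0.279, and cold and dehydration genes did not pass fry's directional or mixed test (adjusted p = 0.221 and 0.0617). With signals set to the dim limit the median of glutathione transferases was 0.47 (camera adjusted p = 0.0327). The medians of the cold and dehydration, glutathione transferase and ATP-citrate lyase lists also depended on scaling. They were 0.998, 1.15 and 1.13 without normalization, and 0.30, 0.45 and 0.43 under median centring. Adjusted over the list alone 3, 4 and 2 of their members rose, and 4, 4 and 2 with the replicate block. In these lists COR27 rose at least 3.22-fold (limma adjusted p = 0.0445, 0.0613 to 0.157 without 1 array, 0.0595 with a prior without a trend, 0.0874 without the filter and 0.0625 with the stricter filter), while GSTU20 and ACLA-1 differed by 1.12 ± 0.27 SE and 0.90 ± 0.25 SE and did not pass (limma adjusted p = 0.0653 and 0.087), though both did with the replicate block (0.0257 and 0.0452) and GSTU20 did without LEC1 induced replicate 2 (0.0294). The brightest member of the ATG8 and ATG3 list, APG8H, differed by 1.51 ± 0.55 SE (limma adjusted p = 0.147, 0.0297 with the block and 0.00933 without LEC1 induced replicate 2). Expansins and xyloglucan endotransglucosylases (median -0.32, 0.22 without normalization, camera adjusted p = 0.179) and UDP-glycosyltransferases (median -0.43, 0.18 without normalization, camera adjusted p = 0.248) did not pass, though the latter did without control replicate 1 (0.0471). Endoplasmic reticulum bodies did not pass either (median 0.23, -0.20 under median centring, camera adjusted p = 0.178). In fry's mixed test, which counts changes either way, endoplasmic reticulum bodies and UDP-glycosyltransferases passed (adjusted p = 0.026 and 0.016). The brightest members of the expansin and endoplasmic reticulum body lists, EXPA4 and PYK10, differed by 0.16 ± 0.31 SE and 0.23 ± 0.20 SE, and by -0.14 and -0.48 under median centring. Among UDP-glycosyltransferases UGT76B1 rose 2.96-fold (limma adjusted p = 0.0429), a call lost without any 1 of the 4 arrays (0.0603 to 0.18), with a prior without a trend (0.0657), without the filter (0.087) and with signals set to the dim limit (0.0506).

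For the rise of seed storage, oleosin and LEA genes, of 15 called probe sets in these lists 15 stayed higher by more than 2 on the log2 scale and past the threshold without normalization, under median centring and with signals set to the dim limit. The 15 were chosen as called rises in these same data. The median of all kept probe sets shifted by only 0.62 without normalization and -0.08 under median centring, so the count could hardly have been lower. It shows only that these rises were larger than the differences between these scalings. Seedlings held at an earlier stage may keep seed transcripts, and storage lipid breakdown genes, tested for this, moved apart. Their median was 0.335 (1.002 without normalization), with AIM1 higher (1.61, or 2.01 without normalization) and ICL lower (-1.09, or -0.75), so a delay cannot be told apart from the induction by these 3 members. An effect of estradiol itself also stays open, since both induced arrays had estradiol and no array had it without the transgene's induction. Induction of an embryo programme by LEC1 remains a hypothesis beside these, and no test here tells it apart from them.

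For the lower organelle-encoded transcripts, the median without normalization was -1.52 for plastid-encoded photosynthesis, -1.0 for plastid-encoded gene expression and -0.735 for mitochondrion-encoded genes, with values within replicates nearest to 0 of -1.06, -0.818 and -0.531, and under median centring the medians were -2.22, -1.70 and -1.43. For plastid-encoded photosynthesis the test was set before the results were seen, and it asked whether the median rose above -0.5. The fitted median was -1.89, and all kept probe sets shifted by only 0.62 without normalization and -0.08 under median centring. The test could thus hardly have come out otherwise. It shows only that this fall was larger than the differences between these scalings. The tests of the other lists were chosen afterwards, and their values are given without a reading. Those of the mitochondrial genes came nearest to 0. Poorer capture of all organelle RNA in the induced samples may lower plastid and mitochondrial transcripts alike, and the plastid median was below the mitochondrial median by different amounts in the replicates, with differences of -0.186 and -0.898, which leaves this open. A lower plastid programme of nuclear and plastid genes stays open too, since the nuclear electron transport list was known to be lower (median nearest to 0 within replicates -0.861, pooled median -0.503 without normalization) before this test was chosen, and so gives it no support. The actin 3' to 5' ratio also differed by group, and its part was not tested for these transcripts or for any other list.

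Poly-A spike RNA was brighter on the replicate 1 arrays in both groups, 4.17 times and 2.68 times. The hybridization spikes had ratios of 0.953 and 1.27, so they differed by less than the poly-A spikes did. This test was chosen after the results were seen, and each ratio rests on 1 array against 1. The values are therefore given without a reading on the cause. The median signal of all probe sets was also higher on the replicate 1 arrays, at 20 against 15.5 in controls and 39.4 against 22.3 in induced seedlings. A generally brighter sample may therefore have a part and is not excluded. A different amount of spike or of sample RNA, or a separate round of amplification, may lie behind the poly-A spike difference and was not tested. No biological explanation was tested.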
